A study of Acipenser dabryanus with 12 samples.

How the data were processed

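RNA was extracted with TRIzol from tissue of fish about 6 months old, with a stated initial weight of 358.64 ± 37.1 g (kind of error not stated), per the labels' protocols. Of 40 fish in 2 ponds, 6 per pond and time were sampled, 1 h before the daily feeding at 16:00 or 1 h after it. RNA of 3 samples per group and time, with an RNA integrity number above 8, went into libraries (TruSeq) sequenced as 125-bp paired-end reads on an Illumina HiSeq instrument, and the cleaned reads were assembled with Trinity, per the labels' protocols. The labels speak of 45 libraries; 12 are analysed here, and whether each pools the 3 samples or stands for 1 of them is not stated. The protocol text describes the dissection and extraction of liver, though the samples are labelled brain, liver and spleen.

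The deposited values are TPM (transcript abundance scaled to a fixed library total) per Trinity gene, 1 column per library, with 2 decimals and a sum of 1000000 within rounding. The quantification tool was not given in the sources used here. TPM divides by each library's own total, so when a few genes take more of it the others fall. TPM keeps no depth, so no counting error can be given. Trinity splits one gene into several IDs in places: 46.72% of the IDs shared their component with another ID, and such IDs can divide reads between them. No reference genome or annotation was used here and the files pair no ID with a name, so the gene lists fixed beforehand could not be tested. Named IDs follow a rule fixed before the data were examined: at most 2 that rose and 2 that fell per comparison, those past the threshold with the largest fold in one direction, or, where none passed, those with a mean of at least 5 TPM and the largest value of the smallest fold over the pairs. Only IDs with the same sign in every pair could be named under this rule. TRINITY_DN126317_c1_g1 was added after its values were seen.

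Groups were taken from the labels. The planned tests named a count model or, for normalized values, limma; because the values are TPM, limma was used. Genes of at least 1 TPM in at least 2 libraries were tested (89972) on log2(TPM + 1) with limma 3.58.1 (trend, robust empirical Bayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Tissues were compared with a 3-coefficient model on 9 residual degrees of freedom, in which diet and feeding state count as spread. Diet and feeding state within tissues were tested in one 9-coefficient model with 3 residual degrees of freedom, which are the diet-by-feeding-state differences of the 3 tissues, and across tissues in a 7-coefficient model with 5. The limma fits were tested on simulated data with 200 changed genes, and camera on a simulated set with a shift and one without. Those 200 genes were drawn from genes with a mean log2(TPM + 1) of at least 5 in the libraries concerned, with independent normal noise. Tissue-enriched sets were tested with camera (preset correlation 0.01, and estimated) and fry. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for summaries and matplotlib 3.10.9 for plots.

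Alternatives were quantile normalization, no filter or a mean of at least 5 TPM, limma without trend, a pseudocount of 0.1, each library left out, the libraries of a tissue alone, and the other factor counted as spread. A filter at a mean of 20 TPM in the tissue, fits without the brain and spleen libraries of the fish oil diet before feeding, a tissue fit with diet and feeding state as a block of 4 levels, and the tissue-enriched sets were chosen after seeing the data. Count-based alternatives were not run, as the values are not counts. For each group of 4 libraries of a tissue, a library far from the others was sought with Dixon's ratio (critical value 0.829).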

Results

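RNA sequencing was applied to brain, liver and spleen of juvenile Yangtze sturgeon (Acipenser dabryanus), a freshwater sturgeon of the upper Yangtze River. The fish had received a diet with either soybean oil, a plant oil, or fish oil, a source of long-chain omega-3 fatty acids, for 7 weeks. Samples were taken 1 h before the daily meal or 1 h after it. The files held 12 libraries, 4 per tissue, with 1 library for each combination of tissue, diet and feeding state. Each diet was given in 1 pond, so diet and pond coincide, and feeding state coincides with the hour of sampling. The labels do not say whether a library came from 1 fish or from several pooled fish. The p-values below measure only the spread between these libraries. For diet and feeding state within tissues, that spread is the diet-by-feeding-state difference, as no combination has a second library. A gene with a real difference of that kind gets a larger error.

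The values were TPM for 280408 genes of a de novo assembly, and the IDs were paired with no gene names. Pathways and cell type markers could therefore not be described by name. Of the assembled genes, 13274 were listed at 0 in all 12 libraries. Brain libraries held 65949 ± 10783 genes of at least 1 TPM (SD, n = 4), spleen libraries 54514 ± 7932 (SD, n = 4) and liver libraries 39633 ± 7116 (SD, n = 4). The 10 highest genes of each library took 11.9% ± 1.94 of all TPM in brain, 17.7% ± 3.18 in spleen and 18.5% ± 3.78 in liver (SD, n = 4 each). The brain library of the fish oil diet before feeding had the most detected genes of the 12, 78832, and the liver library of the soybean oil diet before feeding the fewest, 29749. TPM keeps no sequencing depth, so the depth of each library is unknown and no counting interval is given.

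**Figure D1:**
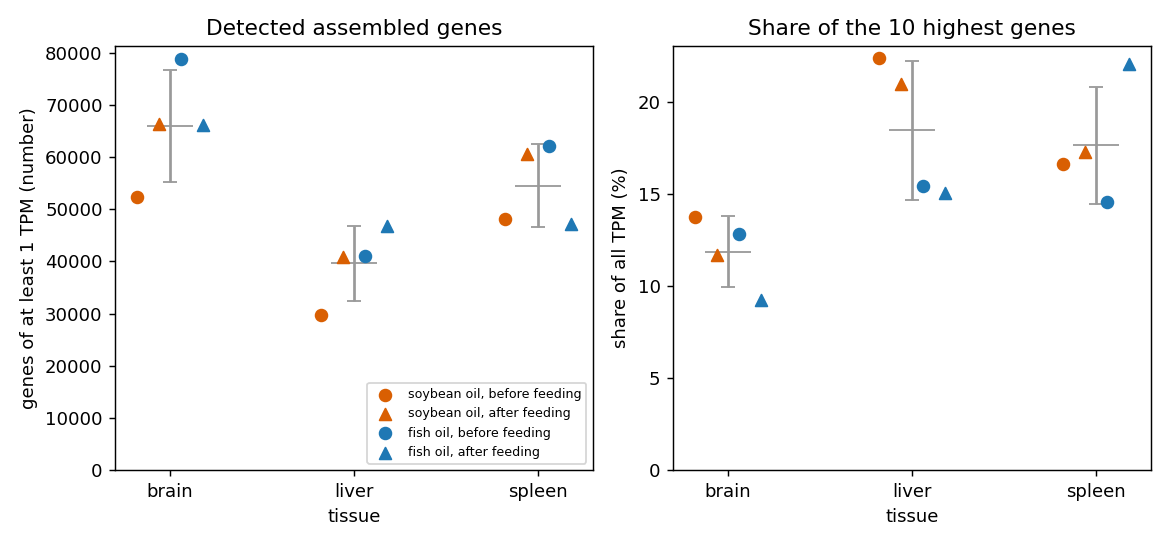
Left, number of assembled genes of at least 1 TPM per library; right, share of all TPM held by the 10 highest genes of each library in percent. Points are single libraries by tissue, diet (colour) and feeding state (shape), with the mean and SD of 4 libraries per tissue in grey; liver libraries held 29749 to 46726 detected genes and brain libraries 52435 to 78832.

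The first comparison asked how the 3 tissues differ. Brain, liver and spleen each had genes that were nearly restricted to them. TRINITY_DN131745_c1_g2 was at 2230 ± 335 TPM in brain, 0.325 ± 0.039 TPM in liver and 0.498 ± 0.326 TPM in spleen (SD, n = 4 each). TRINITY_DN128327_c4_g2 was at 8643 ± 2899 TPM in liver and 4.23 ± 2.99 TPM in brain (SD, n = 4 each). TRINITY_DN125752_c2_g1 was at 373 ± 80.4 TPM in spleen, 0.490 ± 0.702 TPM in brain and 0.298 ± 0.33 TPM in liver (SD, n = 4 each). In limma on log2(TPM + 1), the brain gene was higher than in liver by a log2 fold of 10.71 ± 0.19 (SE; adjusted p = 1.05e-11). The liver gene was lower in brain than in liver, at a log2 fold of -10.83 ± 0.55 (SE; limma adjusted p = 1.25e-08). The spleen gene was lower in brain than in spleen, at a log2 fold of -8.05 ± 0.30 (SE; limma adjusted p = 2.34e-09). All 3 went the same way in each of the 4 pairs of libraries with matching diet and feeding state, which the rule for naming IDs required.

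Of 89972 genes tested, 33586 were higher and 5793 lower in brain than in liver (limma, Benjamini-Hochberg threshold 0.05). Against spleen, brain had 17757 higher and 6840 lower genes. Liver had 7094 higher and 22758 lower genes than spleen. The size of this imbalance rested on scaling, and the rescaling used cannot tell whether its side did. Quantile normalization gives all libraries one distribution, which brings such shares towards balance. After quantile normalization 53.55% of the called genes were higher in brain than in liver, against 85.29% of those called on TPM as deposited. The same share was 52.57% against 72.19% for brain over spleen and 46.77% against 23.76% for liver over spleen. The median gene differed by a log2 fold of 0.60 between brain and liver, 0.14 between brain and spleen and -0.34 between liver and spleen before this scaling. After it the medians were 0.026, -0.071 and -0.046, so that of brain and spleen changed sign. Libraries of the same tissue correlated with a Pearson r of 0.7994 to 0.8918 across genes, and libraries of different tissues with 0.44 to 0.7055, where genes are not independent replicates.

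Sets of tissue-enriched genes, defined after the data were seen, were used to follow each tissue's own genes. A gene entered a set with a mean of at least 10 TPM in the tissue, an adjusted p past the threshold against both other tissues, and at least 8-fold higher values than in each, so the contrast between tissues is largely set by this choice. The liver set of 1037 genes took 53.2% ± 5.32 of all liver TPM (SD, n = 4), and 0.338% ± 0.0582 in brain and 0.280% ± 0.0809 in spleen (SD, n = 4 each). The brain set of 1417 genes took 9.56% ± 0.869 of brain TPM, and the spleen set of 253 genes 6.73% ± 0.840 of spleen TPM (SD, n = 4 each).

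The second comparison asked which genes differ between the soybean oil and the fish oil diet. In liver, the TPM of the most abundant liver genes was higher with soybean oil. The 99 liver-enriched genes with a mean of at least 1000 TPM in liver took 47.1% ± 0.649 of liver TPM with soybean oil and 37.2% ± 0.009 with fish oil (SD, n = 2 each). This was a ratio of 1.28 before feeding and 1.25 after feeding. The most abundant of them, TRINITY_DN126317_c1_g1, singled out after its values were seen, stood at 105492 and 96532 TPM in the soybean oil livers before and after feeding, and at 54590 and 56570 TPM in the fish oil livers. With 2 libraries per diet, an exact two-sided permutation test cannot give a p below 0.333. In limma with the spread shared by the 3 tissues, this gene had a log2 fold of 0.86 ± 1.10 (SE) and an adjusted p of 1. That SE includes the spread of its low values in brain (36.3 to 106 TPM) and spleen (13.5 to 348 TPM). It therefore does not measure the spread between livers. The median of the 1037 liver-enriched genes lay on the other side, at a log2 fold of -0.24, with 461 lower and 186 higher with soybean oil in both feeding states, and it was 0.005 after quantile normalization. Camera gave an adjusted p of 0.0574 for that set, or 0.973 with an estimated correlation.

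**Figure D2:**
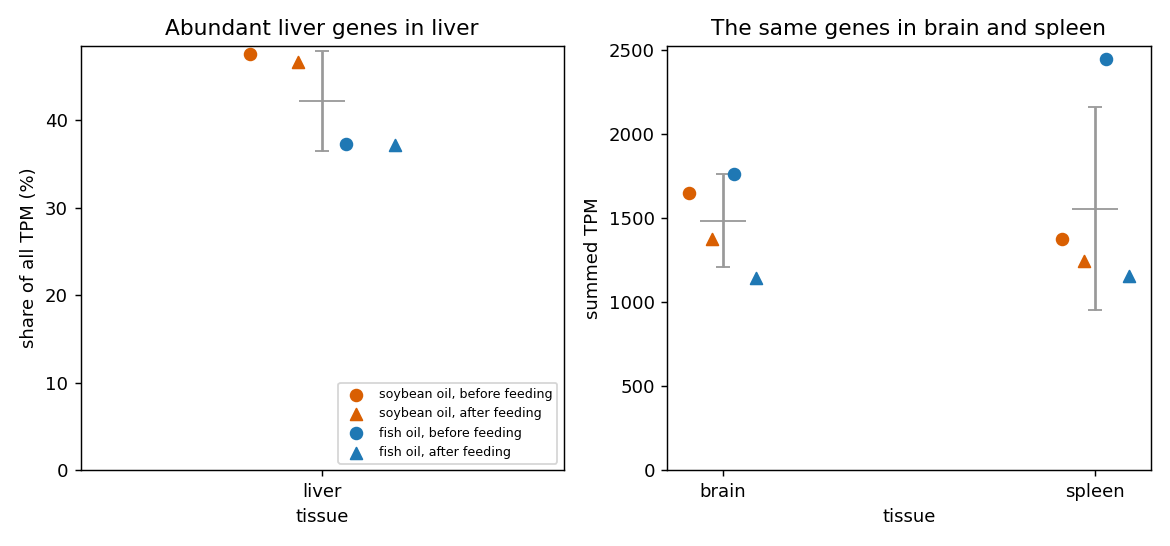
Left, share of all liver TPM held by the 99 abundant liver-enriched genes in percent; right, their summed TPM in brain and spleen. Points are single libraries by diet (colour) and feeding state (shape), with the mean and SD of the 4 libraries of a tissue in grey; both soybean oil livers lie at 46.7% or above and both fish oil livers at 37.2%, and the spleen library of the fish oil diet before feeding holds 2449 TPM.

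No single gene passed the threshold for diet in any tissue. In limma, 0 of 89972 genes were called in brain, liver or spleen; 4432, 2925 and 3291 had an unadjusted p under 0.05, where chance gives 4499. The lowest adjusted p were 0.254, 0.654 and 0.294. These were tests on 3 residual degrees of freedom, made of the diet-by-feeding-state differences. Real differences of that kind would raise the error, so 0 calls do not show that diet had no effect. In data simulated with changes in the more abundant genes, they recovered 82%, 78% and 77% of genes changed by a log2 fold of 4. At a log2 fold of 2 they recovered 2%, 3% and 1%, so smaller differences were not detectable here. Counts above 0 appeared when the spread was set otherwise, with 4, 102 and 88 genes from the libraries of brain, liver or spleen alone, and with 393, 45 and 187 when feeding state was counted as spread. Leaving out any one brain library gave 3145 to 4163 calls in brain, mostly of genes at 0 in liver and spleen; brain then adds no residual degree of freedom, so these calls are no evidence of a diet difference.

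The values of single genes went with diet in some cases without passing the test. In brain, TRINITY_DN142974_c2_g2 was at 13.7 and 10 TPM with soybean oil before and after feeding and listed at 0 in both fish oil libraries (limma adjusted p = 0.254). In liver, TRINITY_DN109301_c3_g1 was at 32.2 and 20.5 TPM with fish oil and listed at 0 in both soybean oil livers (limma adjusted p = 0.654). In spleen, TRINITY_DN118643_c3_g1 was at 55.4 and 21.6 TPM with fish oil and listed at 0 in both soybean oil spleens (limma adjusted p = 0.539). Across the 3 tissues, TRINITY_DN107696_c0_g1 was lower with soybean oil in all 6 pairs of libraries, at a log2 fold of -2.96 ± 0.39 (SE, limma adjusted p = 0.872). Only IDs with one sign in every pair could be named. Of genes with a mean of at least 5 TPM, 3.787% kept one sign over the 6 pairs. Independent pairs with as many genes higher as lower would give 3.125%. The pairs were not so balanced: by tissue and feeding state, 26.25% to 61.96% of genes of at least 5 TPM were higher with soybean oil. The 3.125% is therefore no fair reference, and no excess of agreement can be read from it. Across tissues, 0 genes were called and 3455 had an unadjusted p under 0.05. That test recovered 90% of simulated genes changed by a log2 fold of 2. The simulated changes were placed in the more abundant genes, equal in every tissue and with independent noise. The recovery of lower genes, such as those named here, is therefore unknown.

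Diet folds before and after feeding shared little in most liver genes and more in the abundant ones. In brain and spleen they leaned to opposite signs. Of the genes of at least 5 TPM, 58.62% had the same sign in both feeding states in liver, 43.60% in brain and 36.85% in spleen. The shares of higher genes in each state alone give 56.89%, 51.47% and 44.83% for independent folds. After quantile normalization the observed shares were 51.53%, 40.90% and 38.19%, against 49.89%, 49.82% and 49.60%. Among genes at least 2-fold apart in both states, 64 were higher and 331 lower with soybean oil in liver, and 204 changed sign between the states. After quantile normalization the liver numbers were 85, 150 and 173, and the median liver gene of at least 5 TPM went from a log2 fold of -0.28 to 0.005. In brain the numbers on TPM as deposited were 76, 268 and 613, and in spleen 169, 278 and 1294. After quantile normalization they were 153, 199 and 665 in brain and 184, 273 and 910 in spleen. Across genes of at least 5 TPM, Pearson's r between the diet folds of the feeding states was 0.079 in liver, -0.171 in brain and -0.171 in spleen. Among genes of at least 100 TPM it was 0.337 in liver (785 genes; Spearman's rho 0.304), -0.121 in brain and -0.177 in spleen. The test of whether the diet effect differed between tissues called 0 genes for each of the 3 pairs of tissues. It had an unadjusted p under 0.05 in 3422 genes for brain and liver, 4339 for brain and spleen and 3258 for liver and spleen, and it recovered 0% of simulated genes even at a log2 fold of 4.

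**Figure D3:**
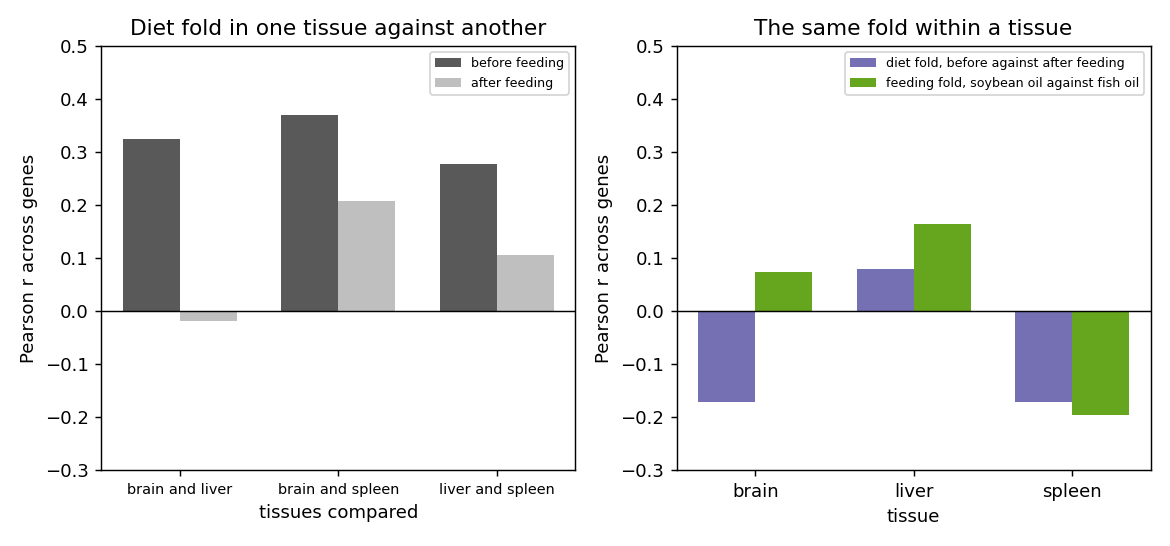
Left, Pearson r across genes of at least 5 TPM between the log2 diet folds (soybean oil over fish oil) of a pair of tissues, before and after feeding; right, Pearson r within each tissue between the diet folds before and after feeding, and between the feeding folds of the diets. The diet folds of different tissues shared an r of 0.277 to 0.369 before feeding, while within a tissue the diet folds of the feeding states had an r of -0.171 to 0.079.

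The third comparison asked which genes differ between fish sampled 1 h after and 1 h before the meal. In brain, the brain-enriched genes were higher after the meal, with a median log2 fold of 0.58 in the soybean oil libraries and 0.34 in the fish oil libraries. Of the 1417 genes, 794 were higher and 90 lower in both diets. Camera with a preset correlation gave an adjusted p of 1.73e-10 over 18 set tests; the adjusted p was 0.441 with an estimated correlation and 0.169 in fry. The median of all brain genes of at least 5 TPM was also above 0, at 0.207, and after quantile normalization the medians were 0.313 for the set and 0.06 for those genes. The same set was lower with soybean oil in brain, at medians of -0.36 before and -0.21 after feeding. In both states 662 genes were lower and 99 higher. Camera gave an adjusted p of 0.00161, or 0.931 with an estimated correlation, and fry gave an adjusted p of 0.199. All brain genes of at least 5 TPM had a median of -0.152 for diet. After quantile normalization their median was 0.038, and that of the set went from -0.331 to -0.2. Liver-enriched genes had a camera adjusted p of 0.0306 for lower values after the meal in brain and in spleen, both 0.973 with an estimated correlation. Their median log2 folds with soybean oil and fish oil were 0 and -0.12 in brain and 0 and -0.28 in spleen, so only the fish oil pairs lay below 0. In spleen, the fish oil library before feeding held 3965 TPM of this set and the other 3 libraries 2100 to 2564 TPM. The other 14 set tests had camera adjusted p of 0.0557 or more.

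No single gene passed the threshold for feeding state. In limma, 0 of 89972 genes were called in brain, liver or spleen, with 7369, 2922 and 3069 at an unadjusted p under 0.05 and lowest adjusted p of 0.253, 0.501 and 0.317. Chance gives 4499, so brain alone lay above it. After quantile normalization the numbers were 6198, 4127 and 2981. Genes are not independent, so the excess in brain carries no p. The simulated recovery was 80%, 77% and 81% at a log2 fold of 4 and 1% at a log2 fold of 2 in each tissue. In liver, TRINITY_DN107831_c3_g5 was at 62.3 and 24.5 TPM before the meal with soybean oil and fish oil, and was listed at 0 and at 0.02 TPM after it (limma adjusted p = 0.501). TRINITY_DN136205_c1_g2 was at 71.8 and 115.0 TPM in liver before the meal and at 3.01 and 0.13 TPM after it (limma adjusted p = 0.51). When the tested genes were limited to those with a mean of at least 20 TPM in the tissue, a choice made after the data were seen, TRINITY_DN107831_c3_g5 was the 1 gene called in liver (limma adjusted p = 0.00734). Its liver mean of 21.7 TPM lay just above that limit. It was at most at 0.1 TPM in every brain and spleen library, so these tissues add almost no spread to its test. The call may rest on that. In brain, TRINITY_DN130348_c7_g1 was at 20.3 and 17.7 TPM after the meal and listed at 0 in both libraries before it (limma adjusted p = 0.253). In spleen, TRINITY_DN120687_c4_g1 was at 23.9 and 37.9 TPM after the meal and listed at 0 before it (limma adjusted p = 0.403).

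Counts above 0 appeared under other settings here too, with 4, 104 and 72 genes from the libraries of brain, liver or spleen alone, and 477, 99 and 204 when diet was counted as spread. Leaving out any one brain library gave 3443 to 4310 calls in brain, again mostly of genes at 0 elsewhere and no evidence of a feeding difference. Across the 3 tissues 0 genes were called and 2606 had an unadjusted p under 0.05 (limma, lowest adjusted p = 0.975). TRINITY_DN138987_c2_g4 was lower after the meal in all 6 pairs of libraries, at a log2 fold of -1.0 ± 0.12 (SE; limma adjusted p = 0.975), for example at 321 and 288 TPM before and 158 and 134 TPM after it in brain. TRINITY_DN112390_c1_g1 was higher after the meal in all 6 pairs (log2 fold 2.29 ± 0.47, SE, limma adjusted p = 0.975), with 614 TPM in 1 spleen library and at most 28.7 TPM in the other 11. Only IDs with one sign in every pair could be named, so this agreement was fixed by the choice. Of genes with a mean of at least 5 TPM, 3.25% kept one sign over the 6 pairs, against 3.125% for independent, balanced pairs. By tissue and diet, 29.81% to 66.39% of genes of at least 5 TPM were higher after the meal, so 3.125% is no fair reference. The tissues of a group may come from the same fish, so the 6 pairs may not be independent.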

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

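All tests of explanations in this part used values computed from the same libraries; the tests of liver RNA in the spleen library and of a diet effect on it, that of detected genes in liver, and those of rescaled liver TPM for each feeding state, were chosen after the result was seen. A library stood apart from the other 3 of its tissue in 7 of 96 groups of 4 values examined. Dixon's ratio gives about 1 in 20 by chance for independent normal values. Here some groups were of IDs picked for folds of the same sign, some were at 0 throughout, and several flags fell on the same library. The 1 in 20 is therefore no fair reference for these flags.

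In the spleen library of the fish oil diet before feeding, 4 liver genes were far above the other 3 spleen libraries. TRINITY_DN126317_c1_g1 stood at 348 TPM against 13.5 to 44.8, TRINITY_DN128327_c4_g2 at 17.4 against 2.38 to 2.74, TRINITY_DN123199_c0_g3 at 20.4 against 0.23 to 1.97, and TRINITY_DN111229_c2_g1 at 4.51 against 0 in all 3. The 99 abundant liver-enriched genes summed to 2449 TPM there. The brain library of the same diet and state was also the highest of its tissue, with 1759 TPM of these genes against 1146 to 1650, and 106 TPM of TRINITY_DN126317_c1_g1 against 36.3 to 49.9. A diet effect on the spleen in both feeding states would raise both fish oil spleens, but the other one summed to 1155 TPM, the lowest of the 4; an effect before the meal alone stays open. Liver RNA in this library may account for the excess, since 85.9% of the 99 genes were higher there than in each other spleen library, by a median of 0.28% of their liver level (quartiles 0.165% and 0.395%); this missed the 90% set as needed, so it stays open, and its source too, because the profile had an r of 0.085 with the liver library of the same diet and state and 0.025 with the closest other one.

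The liver libraries of the soybean oil diet held a larger share of TPM in the most abundant genes, and the other genes were lower. The single highest gene does not account for all of it. With this gene taken out of both the sum and the total, the soybean oil shares were 41.4% and 41.0% before and after feeding. The fish oil shares were then 33.6% and 33.5%. The lowest soybean oil share was thus still 7.37 percentage points above the highest fish oil share. These shares have a smaller total than the shares of all TPM, so the gaps cannot be compared. The part of the gap that this gene carries was not computed. The share also differed between livers with similar numbers of detected genes. The soybean oil liver after feeding and the fish oil liver before feeding had 40932 and 41124 and differed by 9.45 points. This is a single pair that also differs in feeding state. Detection at a TPM limit itself falls when a few genes take more TPM, and depth is unknown, so a role of depth stays open. The lower median of the other 10381 liver genes, -0.289, may come in part from the share taken by the abundant genes, as it was -0.066 once TPM were rescaled without them. After feeding the rescaled median was 0.022, but before feeding it was -0.147, outside the 0.1 set as needed, so that pair stays open. Diet, pond and the fish sampled stay open as origins of the share itself, with 2 libraries per diet.

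TRINITY_DN132379_c4_g2, a spleen gene, stood at 6.39 TPM in the brain library of the fish oil diet before feeding (others 1.57 to 1.84) and at 1.49 TPM in the liver library of the soybean oil diet before feeding (others at most 0.01). TRINITY_DN112390_c1_g1 stood at 614 TPM in the spleen library of the fish oil diet after feeding (others 3.56 to 28.7).

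After the meal both diets moved one way in one tissue and the other way in another in 3 cases, and these differences were not tested. The share of the 10 highest genes changed by a mean of -2.83 percentage points in brain and 4.07 in spleen, and by -0.886 in liver. The spleen mean rests on the fish oil library after feeding, at 22.1% against 14.6% before, while the soybean oil libraries were at 17.3% and 16.6%. The summed TPM of the brain-enriched genes changed by a mean of 14890 in brain and -379 in spleen.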

How the results depend on the processing

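The total counts for the tissue comparisons and the 0 calls for diet and feeding state stayed within 1.5 times of the reported values under quantile normalization, no filter, limma without trend and a pseudocount of 0.1. The counts by direction moved further under quantile normalization. For brain and liver, 15992 genes were then higher and 13874 lower in brain, against 33586 and 5793, and 21743 calls were shared. With a mean of at least 5 TPM, 17843 genes were tested and fewer were called for that reason: 13249 for brain and liver, 7635 for brain and spleen and 12293 for liver and spleen. Leaving out 1 library gave 35762 to 41516, 21905 to 25614 and 26125 to 30834 calls for these tissue pairs, and 0 for diet and feeding state in liver, in spleen and across tissues. For brain it gave 3145 to 4163 calls for diet and 3443 to 4310 for feeding state, whichever brain library was left out, and 0 to 2430 and 0 to 2819 for the diet difference between brain and liver and between brain and spleen. With 3 brain libraries the brain adds no residual degree of freedom. Of the calls for diet and feeding state in brain, 69.16% to 82.32% were genes at 0 in all liver and spleen libraries. For the diet difference between tissues this share was not computed. Such genes made up 5.70% of the genes tested and had a median SE of at most 0.0801 against 0.494 to 0.495 over all genes tested. The calls for diet and feeding state in brain are therefore taken as an artefact of that model. Genes at 0 outside liver or outside spleen kept a median SE of 0.374 to 0.379 and 0.331 to 0.335 when a library of that tissue was left out; why these differ from brain was not tested. Brain, liver and spleen alone gave 4, 102 and 88 calls for diet and 4, 104 and 72 for feeding state. With the other factor counted as spread they were 393, 45 and 187 for diet and 477, 99 and 204 for feeding state; the cause was not tested. The added filter at 20 TPM gave 1 call for feeding state in liver, of a gene at most at 0.1 TPM in brain and spleen. The agreement of the feeding effect between diets in liver went from an r of 0.054 to 0.165 with the filter at 5 TPM; the cause was not tested. Detected genes at 0.1 TPM were 125538 in brain, 90827 in liver and 106162 in spleen, by the lower limit.

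TRINITY_DN126317_c1_g1 changed sign when a library was left out, never past the threshold. Its log2 fold ranged from -1.20 to 0.45 for diet in brain, -2.93 to 1.55 for diet in spleen, -0.39 to 0.51 for diet across tissues, -1.53 to 0.12 for feeding state in brain and -0.128 to 0.051 for feeding state in liver. Without the brain and spleen libraries of the fish oil diet before feeding it was 0.93 across tissues, and the tissue calls were 37854, 19974 and 26957, with 0 for diet and feeding state across tissues. With diet and feeding state as a block of 4 levels, added after seeing the data, the tissue calls were 40096, 24701 and 30533. The labels give no replicate numbers that pair libraries. Depth is unknown for TPM.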

Other observations

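The tests of low genes and of exchanged labels, and those over splits of the samples, were chosen after the result was seen; the one with quantile normalization was set before its result was known. The diet folds of different tissues resembled each other before feeding, with an r across genes of at least 5 TPM of 0.324 for brain and liver, 0.369 for brain and spleen and 0.277 for liver and spleen. After feeding these were -0.019, 0.208 and 0.105. Within a tissue, the diet folds before and after feeding had an r of -0.171, 0.079 and -0.171 in brain, liver and spleen; in liver it was 0.128 at 20 to 100 TPM and 0.337 at 100 TPM or more. A comparison on the same genes, of at least 100 TPM in both tissues, was added after the data were seen. For brain and spleen (425 genes) r was 0.693 between the tissues before feeding, and -0.022 in brain and -0.291 in spleen between the states. For brain and liver (290 genes) it was 0.430 between the tissues and 0.435 in liver between the states, and for liver and spleen (283 genes) 0.054 and 0.453, so the contrast did not hold for liver at this level. Before feeding the fish oil library had more detected genes in all 3 tissues (78832 against 52435 in brain, 41124 against 29749 in liver, 62193 against 48131 in spleen), and after feeding only in liver (66103 against 66426, 46726 against 40932, 47226 against 60507). Genes are not independent replicates, so these values carry no p. The lowest r between tissues before feeding was 0.349 among genes of at least 20 TPM (0.054 at 100 TPM, for liver and spleen). Noise independent between libraries would not give a positive r, so this cannot test sampling noise of low genes. Such noise can lower the r between feeding states, and this stays open for liver, where that r rose with abundance. In brain and spleen that r was still -0.121 and -0.177 at 100 TPM or more. A different distribution of values is a poor account of the r between tissues, since the lowest was 0.263 after quantile normalization. Exchanged labels of the spleen libraries after feeding stay open. They would turn the r of the spleen with the other tissues negative, where the lower was 0.105, but this needs a fold shared by the tissues after feeding, and brain and liver had -0.019. Turning that spleen pair alone gave 10542 genes at an unadjusted p under 0.05 in limma for diet across tissues, against 3455 with the labels as given. Turning the brain pair after feeding as well gave 13378, and turning all 3 pairs after feeding gave 10710. The rise therefore does not single out exchanged spleen labels. The shared part may be a diet difference present before the meal, or may come from whatever sets the number of detected genes, or from the fish or handling behind each pair of libraries; these remain untested.

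Splits of the libraries into groups of the same sizes gave far fewer genes than the tissues did. The real split was the only 1 of 35 to give as many genes for each pair of tissues: 39379 for brain and liver (highest other split 5), 24597 for brain and spleen (18) and 29852 for liver and spleen (8). With 35 splits the share could not fall below 0.02857. Every other split mixed both tissues in each group, which widens the spread, so few calls there were likely beforehand. For diet and for feeding state across the 3 tissues, the real count was 0, so all 32 of 32 splits gave as many (highest other split 0) by construction and the count says nothing about chance. At an unadjusted p under 0.05, 8 of 32 splits gave as many genes as diet and 15 of 32 as many as feeding state, with up to 13378 and 12350 genes in other splits. The split that follows diet and feeding state together, with the sign turned in the 3 tissues between states or diets, ranked 2 of 32 in both cases, with 10710 and 9924 genes. The highest split in both cases turned brain and spleen and not liver.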
